A study of Xenopus laevis with 11 samples.

How the data were processed

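Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Xenopus laevis embryos at Nieuwkoop-Faber (NF) stage 10.5, the early gastrula. Per the labels' protocols, pooled embryos were cross-linked with formaldehyde, homogenised and sonicated before precipitation with an antibody. The series holds 11 samples: 2 replicates each for H3K4me3, H3K4me1, H3K36me3, p300 and RNA polymerase II, and 1 input. Peak lists of 4 samples were analysed, both replicates of H3K4me3 and both of p300. The 7 other samples were not analysed here. Samples were grouped by the target and the replicate number in their titles. The labels do not say whether the replicates came from separate clutches of embryos, so their spread may be technical. They name a pair of sequencing instruments without saying which library ran on which, so an instrument batch could not be examined.

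The authors deposited 6 peak lists: 1 per replicate and 1 series-wide list per target. Per the submitters' processing notes, the tools were BWA 0.7.10-r789, MACS2 2.1.0.20140616 and bedtools, with no settings given. The genome build, the peak threshold, the treatment of duplicate reads and the control used for peak calling are not given in the sources used here. The lists have no header. They hold chromosome or scaffold name, start and end, and the p300 lists also hold a text name made of an interval. There is no signal, score or p-value, so the values used were the positions and widths of the peaks as deposited. Read depth is unknown, and differences in depth, fragment length or threshold between libraries can change which peaks were called. The series-wide lists were compared with the replicate lists. Each of the 24948 H3K4me3 and 25010 p300 series-wide intervals was identical, to the base, to an intersection of a replicate 1 peak with a replicate 2 peak. A series-wide peak is therefore the part of a peak that both replicates cover, and its width is at most that of the narrower call. This construction also leaves short pieces: 43 H3K4me3 and 186 p300 intervals were narrower than 50 bp.

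The files name their chromosomes 1L to 9_10L and 1S to 9_10S, with the remaining sequence in scaffolds. The gene table at hand is for assembly Xenopus_laevis_v10.1, which describes another set of positions: on 18 of 18 chromosomes its genes reached past the last peak, and 7038 of its 44456 genes lay wholly beyond it. It was therefore not used for positions, and gene names, distances to transcription start sites, homeologous gene pairs, gene lists and sequence motifs were not analysed here. Coordinates are given 1-based in the unnamed build of the files. Because chromosome lengths of that build were not at hand, the end of the last peak in any list served as the span of a chromosome, which is a lower bound of its length.

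Overlaps of at least 1 bp were counted with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Overlaps on the 18 L and S chromosomes were set against 1000 random circular shifts of the second list within each chromosome, which keep the spacing of its peaks. The p is one-sided, and 0.001 is the smallest it can be. Shares carry Wilson 95% intervals, which treat peaks as independent and cover counting error only. The L and S chromosomes were compared as the log2 ratio of peak counts within each of the 9 homeologous pairs, with a two-sided exact sign-flip permutation test over the pairs. The smallest p this test can give is 0.00391. It measures how regular a difference is across chromosomes, not across batches of embryos. Benjamini-Hochberg adjustment was applied over the 4 subgenome tests fixed before the data were examined; the family was set when the values were adjusted, after they had been seen, and values over 5 tests, with an added test of H3K4me3 peaks that hold p300, are given beside them where the call is close. Spreads over pairs are SD. The comparisons of peaks called in a single replicate, of gaps to H3K4me3, of positions inside H3K4me3 peaks, of width classes, of densities per Mb and of the replicates' L to S ratios were added after the data had been seen.

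The functions were tested on simulated data. A simulated p300 list of 23017 peaks had 40.7% of its peaks inside simulated H3K4me3 peaks when read base by base, and the overlap count returned 40.7%. Of 100 independent lists, 5 had a shift p at or under 0.05. Those lists were placed evenly, held far fewer p300 peaks than the real list and were tested with fewer shifts. They therefore do not show how the shift p behaves for lists whose peaks are grouped along the chromosomes. A planted log2 L to S ratio of 0.4 gave an exact p under 0.05 in 200 of 200 runs, and no difference gave it in 11 of 200.

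Alternatives fixed before the data were examined included an overlap of 50% of the shorter peak and the same number of widest peaks from both replicates. Also fixed then were each replicate list in place of the series-wide list, blocking on the replicate number, and p300 within 1 kb of H3K4me3. Covered bases in place of counts, merging of peaks closer than 1 kb and a stricter threshold were fixed as well. The lists held no scores, so the wider 50% of each list took the place of the stricter threshold once they had been read. Shifts limited to 50 to 500 kb, counts per Mb of span, removal of pieces under 50 bp and leaving out each chromosome pair were added after seeing the data. Regions are named by a rule also fixed beforehand: the 3 widest peaks and the 3 densest non-overlapping windows of 100 kb of each series-wide list. The rule's 3 highest-scoring peaks do not exist in lists without scores.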

Results

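Peaks of H3K4me3, the trimethylation of histone H3 that marks active and poised promoters, and of p300, an acetyltransferase coactivator bound at enhancers and promoters, were compared in whole NF stage 10.5 embryos, with 2 replicates per target. For H3K4me3, 32821 peaks were called in replicate 1 and 27267 in replicate 2. The p300 libraries differed more, with 35127 peaks in replicate 1 and 58614 in replicate 2. The series-wide lists held 24948 H3K4me3 peaks covering 32.05 Mb and 25010 p300 peaks covering 6.19 Mb. H3K4me3 peaks had a median width of 1076 bp (quartiles 628 and 1647 bp) and p300 peaks of 215 bp (quartiles 165 and 295 bp). Read depth is unknown, so the number of peaks was taken as each list's size and not as a level of binding.

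The replicates were first compared with each other. H3K4me3 peaks recurred in most places: 91.2% of the replicate 2 peaks (95% interval 90.8 to 91.5%) overlapped a replicate 1 peak, and 73.8% of the replicate 1 peaks (73.3 to 74.3%) overlapped a replicate 2 peak. For p300, 70.8% of the replicate 1 peaks (70.3 to 71.3%) recurred in replicate 2, but only 41.7% of the larger replicate 2 list (41.3 to 42.1%) recurred in replicate 1. When the same number of widest peaks was taken from both p300 lists, the shares on the L and S chromosomes were 57.9% and 53.6%; lists of equal size give similar shares in both directions by construction. Shared bases made up 67.7% of all bases covered by either H3K4me3 replicate and 31.5% for p300. On the L and S chromosomes the overlaps were 28.1-fold and 28.8-fold above shifted lists for H3K4me3, and 61.2-fold and 60.7-fold for p300. Each had the smallest permutation p that 1000 shifts can give, 0.001. The shifted shares were 2.65% and 3.18% for H3K4me3 but 1.19% and 0.676% for p300. The folds therefore do not rank the targets by how well their replicates matched. Across peaks with 1 partner, which are not independent replicates, widths in the replicates had a Spearman rho of 0.88 for H3K4me3 (23522 peaks) and 0.55 for p300 (24747 peaks).

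The p300 peaks found in a single replicate overlapped H3K4me3 to different extents in the 2 libraries. On the L and S chromosomes, 8447 peaks were called in replicate 1 alone, and 26.9% of them (25.9 to 27.8%) overlapped a series-wide H3K4me3 peak, close to the 30.1% (29.6 to 30.7%) of the replicate 1 peaks that recurred. Of the 32339 peaks called in replicate 2 alone, 9.75% (9.43 to 10.1%) overlapped H3K4me3, against 30.3% (29.7 to 30.9%) of the replicate 2 peaks that recurred. Both single-replicate classes lay above shifted H3K4me3 lists, which gave 1.39% and 1.40% (permutation p = 0.001, the smallest possible, in each). The H3K4me3 peaks called in 1 replicate alone were narrow, with a median of 376 bp in replicate 1 and 266 bp in replicate 2, compared with 1465 and 1179 bp for the peaks that recurred.

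The second comparison asked how often p300 lay at H3K4me3-marked regions. Of 23017 series-wide p300 peaks on the L and S chromosomes, 6928 overlapped H3K4me3, or 30.1% (29.5 to 30.7%), which was 21.03-fold above the 1.43% of shifted lists (permutation p = 0.001, the smallest possible). The other 16089 p300 peaks, 69.9%, lay outside the series-wide H3K4me3 list. In the opposite direction, 5597 of 22191 H3K4me3 peaks, or 25.2% (24.7 to 25.8%), overlapped p300, 18.6-fold above shifted lists (permutation p = 0.001). The share of p300 peaks at H3K4me3 was 38.6% between the replicate 1 lists and 18.8% between the replicate 2 lists, so it depended on the library by more than its counting error. With p300 replicate 2 alone against the series-wide H3K4me3 list it was 18.2%, 12.5-fold above shifted lists, and with p300 replicate 1 alone it was 29.3%, 20.4-fold above. The share of series-wide H3K4me3 peaks with p300 was 36.1% with p300 replicate 2 alone, 10.8-fold above shifted lists, and 32.5% with replicate 1 alone, 17.7-fold above. Between the replicate 2 lists the excess was 11.96-fold for p300 and 10.3-fold for H3K4me3.

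**Figure D1:**
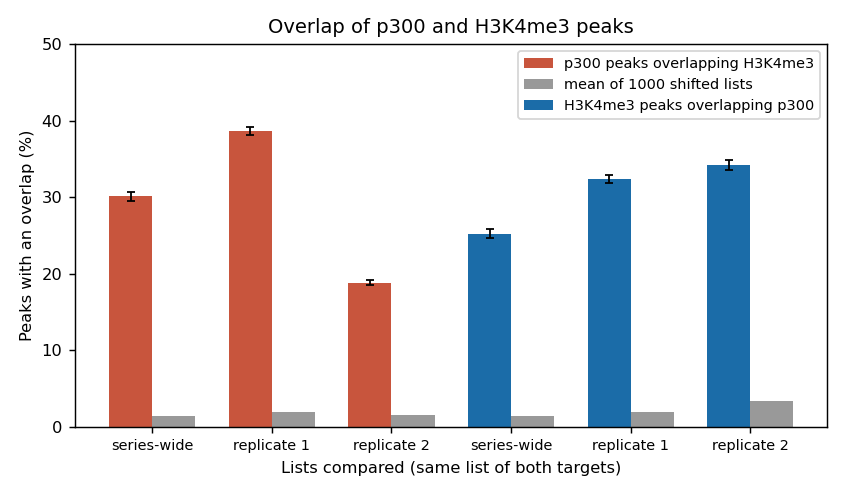
Share of p300 peaks (red) that overlapped H3K4me3 and of H3K4me3 peaks (blue) that overlapped p300, in percent of the peaks on the L and S chromosomes, for the series-wide lists and for each replicate number; error bars are Wilson 95% intervals and grey bars are the means of 1000 shifted lists. Each share stands far above its grey bar, and the p300 share runs from 18.8% in the replicate 2 lists to 38.6% in the replicate 1 lists.

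The p300 peaks outside H3K4me3 were nevertheless close to it. Their median gap to the nearest H3K4me3 peak was 17.7 kb (quartiles 5.31 and 48.8 kb), compared with 48.9 kb for shifted H3K4me3 lists, and 36.6% of them lay within 10 kb, compared with 16.3% (permutation p = 0.0099 for both, the smallest that 100 shifts can give). The p300 peaks at H3K4me3 were somewhat wider than those outside it, with medians of 244 bp (quartiles 178 and 336 bp) and 204 bp (quartiles 162 and 277 bp). H3K4me3 peaks with p300 had a median width of 1475 bp, and those without p300 of 1043 bp. Within H3K4me3 peaks wider than 1000 bp, the 4992 p300 centres were spread over the whole peak: with each peak divided into 10 equal parts, the outermost parts held 7.11% and 7.17% of them, and each of the 8 parts between held 9.84% to 11.9%.

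Broad H3K4me3 peaks most often held p300. The series-wide H3K4me3 peaks were split by width into 10 classes of equal number, numbered from the narrowest. In class 10, from 2556 to 9781 bp, 58.7% (56.6 to 60.7%) overlapped p300. The share was 18.9% (17.3 to 20.6%) in class 5, with a median width of 1039 bp, and 13.2% (11.9 to 14.7%) in class 1. Per kb of H3K4me3, class 10 held 0.264 p300 centres (Poisson 95% interval 0.253 to 0.275) and classes 4 to 9 together held 0.181 (0.175 to 0.188). The density was highest, 0.385 per kb (0.347 to 0.426), in class 2, between 302 and 581 bp. Intersection of the replicates trimmed the peaks, so the narrow classes include fragments of wider calls.

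**Figure D2:**
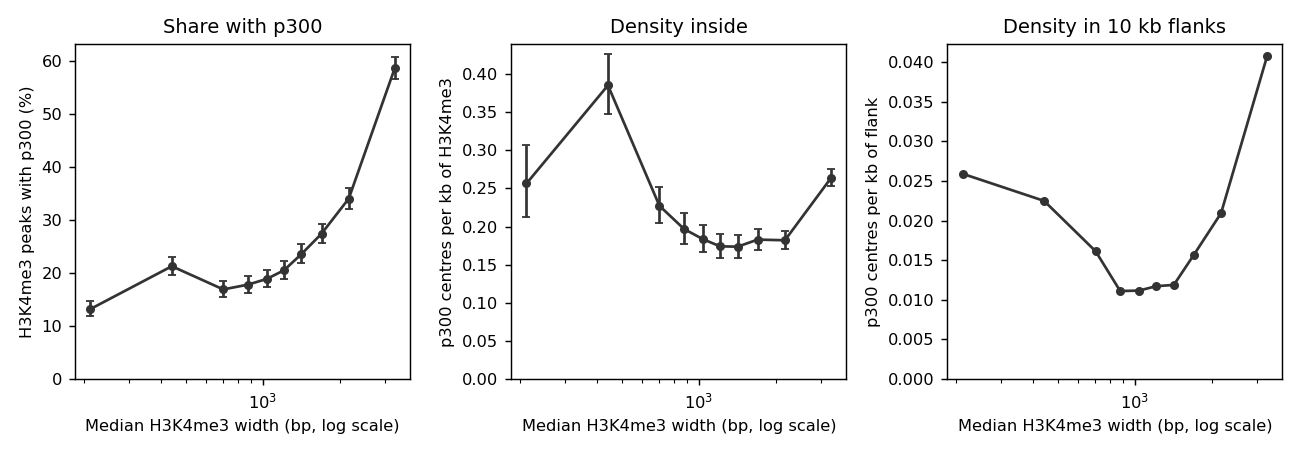
Series-wide H3K4me3 peaks split by width into 10 classes of equal number, plotted by median width (bp, log scale) against the percent that overlapped p300 (left, Wilson 95% intervals), the p300 centres per kb inside the peaks (middle, Poisson 95% intervals), and the p300 centres outside H3K4me3 per kb in the 10 kb on either side (right, without intervals). The share reached 58.7% in class 10, whose flanks held 0.0408 p300 centres per kb.

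The third comparison was between the subgenomes. Xenopus laevis is an allotetraploid whose chromosomes come in homeologous pairs, a long (L) and a short (S) member, each from a different ancestral species. Both marks were more numerous on the L chromosomes. The series-wide H3K4me3 list had 12509 peaks on L and 9682 on S, with a mean log2 ratio of 0.37 ± 0.09 (SD over 9 chromosome pairs), or 1.29-fold. The p300 list had 13268 on L and 9749 on S, a mean log2 ratio of 0.44 ± 0.08, or 1.36-fold. A further 2757 H3K4me3 and 1993 p300 series-wide peaks lay on scaffolds, whose names give no subgenome, and were not counted. Their assignment to L or S could change these ratios. L was higher in 9 of 9 pairs for each target (exact sign-flip p = 0.00391, the smallest possible, and 0.00781 after Benjamini-Hochberg adjustment over 4 tests). The H3K4me3 ratio ranged from 0.24 in pair 2 to 0.49 in pair 3, and the p300 ratio from 0.31 in pair 5 to 0.57 in pair 1.

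The L chromosomes were also longer, with spans exceeding those of S by a mean log2 ratio of 0.27 ± 0.10. This held in 9 of 9 pairs, with the same exact sign-flip p of 0.00391 as the counts. The test of counts therefore does not separate a difference between the subgenomes from chromosome length. Per Mb of span, the series-wide H3K4me3 ratio was 0.10 ± 0.09 (exact p = 0.0117, L denser in 8 of 9 pairs) and the p300 ratio 0.17 ± 0.08 (exact p = 0.00391, 9 of 9 pairs). The replicates gave 0.11 and 0.09 for H3K4me3. For p300 they gave 0.15 in replicate 1 (exact p = 0.00391) and 0.03 in replicate 2 (exact p = 0.344), so a higher p300 density on L was seen in replicate 1 and the series-wide list but did not pass in replicate 2. Chromosome pair 7 was an exception for H3K4me3, with 8.44 peaks per Mb on 7L and 8.75 on 7S. In the series-wide lists the densest chromosomes were 9_10L for H3K4me3, with 11.5 peaks per Mb, and 8L for p300, with 12.3, whereas p300 replicate 2 alone was densest on 8S, with 27.7. The lowest series-wide densities were 7.13 H3K4me3 peaks per Mb on 5S and 7.16 p300 peaks per Mb on 1S.

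**Figure D3:**
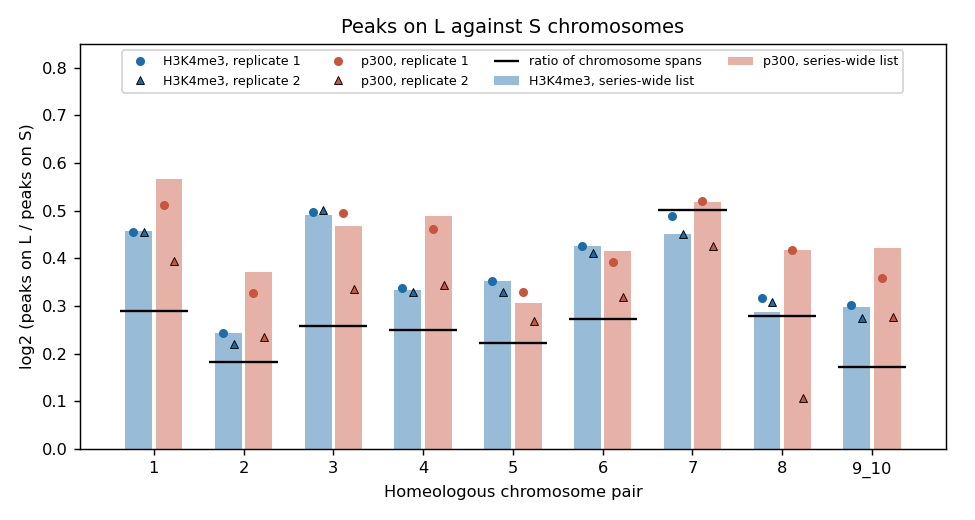
Log2 ratio of peak counts on the L chromosome to those on its S homeolog for the 9 chromosome pairs, for H3K4me3 (blue) and p300 (red); bars are the series-wide lists, circles replicate 1, triangles replicate 2, and black lines the log2 ratio of the chromosome spans. The bars are above 0 in all 9 pairs, and the p300 replicate 2 triangles lie below the replicate 1 circles in each pair, furthest in pair 8.

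The L to S ratio did not differ reproducibly between p300 and H3K4me3. In the series-wide lists it was higher for p300 by 0.07 ± 0.08 on the log2 scale (6 of 9 pairs, exact p = 0.0391), which did not pass after adjustment (0.0521 over the 4 planned tests, 0.0651 over 5). Between the replicate 1 lists the difference was 0.04 ± 0.06 (exact p = 0.0625), and between the replicate 2 lists it had the opposite sign, -0.06 ± 0.08 (exact p = 0.0391). The p300 replicates themselves differed by more than this: the log2 ratio was 0.42 in replicate 1 and 0.30 in replicate 2, lower in replicate 2 in 9 of 9 pairs (mean difference 0.12 ± 0.08, exact p = 0.00391). For H3K4me3 the replicates differed by 0.02 ± 0.01 (exact p = 0.0117). In pair 8, p300 replicate 2 had 2952 peaks on 8L and 2740 on 8S, a log2 ratio of 0.11, whereas replicate 1 had 2030 and 1520, a ratio of 0.42.

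The division of p300 peaks between H3K4me3-marked and other regions was measured on each subgenome. Outside H3K4me3 lay 69.9% of the p300 peaks on L (69.1 to 70.7%) and 69.9% on S (69.0 to 70.8%), with a mean difference over the pairs of -0.01 ± 1.44 percentage points (exact p = 0.984). The L to S ratio was 0.44 ± 0.09 for p300 peaks outside H3K4me3 and 0.44 ± 0.10 for those at H3K4me3. With p300 replicate 2 alone the difference was -1.89 percentage points, a lower share on L (exact p = 0.00391), and with replicate 1 alone it was 0.076 (exact p = 0.855). H3K4me3 peaks with p300 made up 25.7% on L and 24.6% on S, a mean difference of 0.97 ± 1.96 percentage points (exact p = 0.176).

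Single regions were named by width and by density. The widest series-wide H3K4me3 peak lay on chromosome 2S from 128313726 to 128323506 (9781 bp) and overlapped p300. The next 2 were on unplaced sequence, on Scaffold22 from 1877116 to 1886322 (9207 bp), where 4 p300 peaks of replicate 1 and 0 of replicate 2 were centred, and on Scaffold29 from 2909534 to 2918422 (8889 bp), which overlapped p300. The widest p300 peaks lay on 1S from 108752011 to 108753686 (1676 bp), on Scaffold73 from 18437 to 20011 (1575 bp) and on 8S from 26821639 to 26823187 (1549 bp). Those on 1S and 8S overlapped H3K4me3, and that on Scaffold73 did not.

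The densest p300 window of 100 kb was on chromosome 3L from 136419612 to 136519611. It held 35 series-wide p300 peaks, 38 in replicate 1 and 40 in replicate 2, against a mean of 0.918 series-wide peaks per 100 kb of span. It held 11 series-wide H3K4me3 peaks. The next was on 7S from 16850350 to 16950349, with 31 p300 and 9 H3K4me3 peaks. It was followed by 2L from 75983165 to 76083164, with 30 p300 and 10 H3K4me3 peaks. In the 2L window the replicates had 32 and 26 p300 peaks, and 9 H3K4me3 peaks each. Its series-wide counts can therefore hold more than 1 piece of a call. The densest H3K4me3 window was also on 3L, from 129114368 to 129214367, with 18 H3K4me3 and 7 p300 peaks, against a mean of 0.885 H3K4me3 peaks per 100 kb. The other 2 windows, each with 14 H3K4me3 peaks, were on 3L from 136382944 to 136482943, with 28 p300 peaks, and on 6L from 39598219 to 39698218, with 1 p300 peak. The 3L window that starts at 136382944 overlapped the densest p300 window, so this region was dense in both marks, whereas the 6L window held 1 series-wide p300 peak, with 1 in replicate 1 and 9 in replicate 2.

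**Figure D4:**
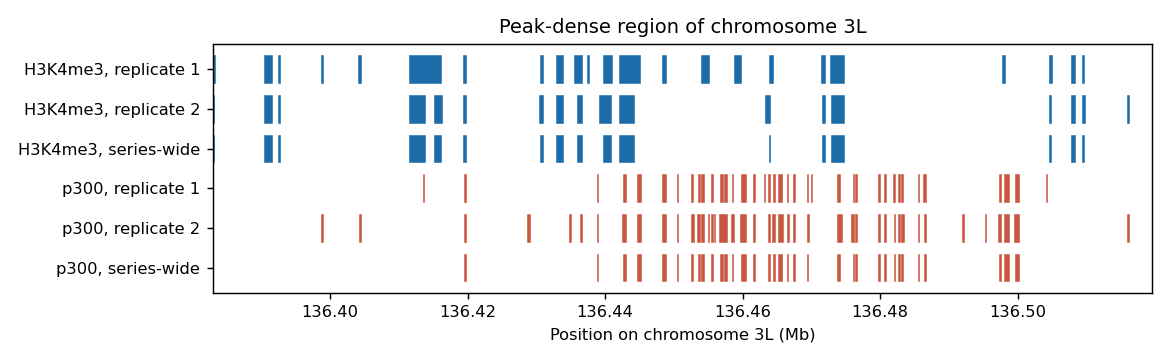
Map of the peak-dense region of chromosome 3L (position in Mb, unnamed build of the files), with H3K4me3 peaks (blue) and p300 peaks (red) drawn to scale for each replicate and the series-wide lists. The window from 136419612 holds 35 series-wide p300 peaks and 11 H3K4me3 peaks, and most p300 peaks recur in both replicates.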

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

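The tests in this part were chosen after the results were seen, except the planned test of the difference between p300 and H3K4me3; the test of distance to shared p300 peaks was prompted by the low ratio of the replicate 2 peaks, and its prediction was written before its own value was seen. The difference between p300 and H3K4me3 in the L to S ratio, 0.071 on the log2 scale in the series-wide lists, was picked out because the same contrast of chromosomes gave different values for the 2 targets (exact p = 0.0391 over 9 pairs, 0.0521 after adjustment over 4 tests). The data argue against calls that follow chromosome length as the whole source of the series-wide p300 ratio of 0.44. Such calls would give about 0 per Mb of span, and the value was 0.17 ± 0.08 (SD, 9 of 9 pairs, exact p = 0.00391). For p300 replicate 2 alone the value was 0.03 (exact p = 0.344), so such calls are not excluded for that list. This test cannot bear on the difference between the targets. Calls that follow span would give the span ratio of 0.27, below the 0.37 of H3K4me3. The choice of p300 library may account for the difference between the targets, which was -0.064 between the replicate 2 lists and 0.043 between the replicate 1 lists. A subgenome preference of p300 sites stays open and was not tested beyond these lists.

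The 32339 p300 peaks called in replicate 2 alone had a log2 L to S ratio of 0.20, lower than the 0.44 of its recurring peaks by 0.24 ± 0.12 (SD, 9 of 9 pairs, exact p = 0.00391), and per Mb of span their ratio was -0.07, denser on S (exact p = 0.0469), against 0.17 for the recurring peaks. For replicate 1 the difference between recurring and single peaks was 0.06 ± 0.12 (6 of 9 pairs, exact p = 0.164). Background spread evenly over the chromosomes as the whole source is excluded by their overlap with H3K4me3, 9.75%, where the highest of 1000 shifts reached 1.61%. Weaker sites in the neighbourhood of shared sites were considered: 17.7% lay within 5 kb of a p300 peak found in both replicates. That was above the highest of 200 local shifts, 8.91%, and below the 27.2% of peaks in replicate 1 alone. Nearness to shared peaks does not account for the low ratio. Shared peaks had 0.44, and the peaks in replicate 1 alone, more often near them, had 0.38. Whether the sites were weaker was not measured, because the lists hold no scores. A mixture of weak sites and background stays open, and with unknown depth and threshold it cannot be resolved from the lists.

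The high p300 overlap of the widest H3K4me3 peaks was weighed because a longer interval meets more peaks by chance. Width alone was excluded as the whole cause for the widest 10% of peaks (class 10), which held 1.45 times as many p300 centres per kb as classes 4 to 9 (mean log2 ratio over the 9 pairs 0.52 ± 0.11, and 0.42 ± 0.11 against classes 1 to 9, each above 0 in 9 of 9 pairs, exact p = 0.00391), although the narrow classes 1, 2 and 3, with 0.257, 0.385 and 0.227 per kb, also lay above the 0.181 of classes 4 to 9, so a high density was not particular to broad peaks. A p300-rich neighbourhood is a candidate explanation: p300 peaks outside H3K4me3 were denser in the 10 kb flanks of class 10 than of classes 4 to 9 by a mean log2 ratio of 1.57 ± 0.15 (SD over 9 chromosome pairs, 2.98-fold, 9 of 9, exact sign-flip p = 0.00391, the smallest possible). Flank counts took p300 outside the series-wide H3K4me3 list, so they can include peaks inside an H3K4me3 call of 1 replicate. How many did was not measured. The flanks of narrow peaks were dense as well, with 0.0259 and 0.0225 centres per kb of flank in classes 1 and 2. These lay above the 0.0111 to 0.0209 of classes 4 to 9 and below the 0.0408 of class 10. Whether gene content, chromatin accessibility or mappability underlies both was not tested, and the design gives no group that would test a biological cause.

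Peaks on unplaced scaffolds were outside the chromosome comparisons and are given as values without a test. They made up 11.1% of the series-wide H3K4me3 peaks (10.7 to 11.4%) and 7.97% of the p300 peaks (7.64 to 8.31%). The p300 replicates differed here as well, with 10.8% in replicate 1 and 6.48% in replicate 2, compared with 11.9% and 11.4% for H3K4me3.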

How the results depend on the processing

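Of 79 recomputed values, 62 kept their direction and their side of the threshold or moved by less than the spread between replicates. This covers each overlap between replicates and between targets (with 200 shifts, permutation p = 0.005, the smallest possible, each time) and the excess of H3K4me3 and p300 peak counts on L; per Mb of span the excess passed for the series-wide lists, but for p300 replicate 2 alone it was 0.03 (exact p = 0.344). For shares, a kept direction meant only that the value stayed above shifted lists, whatever its size. The series-wide lists lay wholly within the replicate lists by construction, so their rows could not change. The p300 share at H3K4me3 ran from 18.2 to 40.1% when single replicate lists were used. The lower value rested on p300 replicate 2 and the upper on H3K4me3 replicate 1. Within 1 kb the share was 35.5%. The labels do not pair replicate numbers across targets. The log2 ratios of replicate 1 to replicate 2 in windows of 5 Mb correlated at r = 0.17 between the targets (489 windows), which is not enough to pair 2 numbers. With the replicate block the p300 minus H3K4me3 difference in the L to S ratio became -0.010 (exact p = 0.562), and the p300 share at H3K4me3 was 28.7%. That difference ranged from -0.070 (without p300 replicate 1) to 0.077 with single replicate lists, was 0.062 without H3K4me3 replicate 2 (exact p = 0.0547), and was 0.12 in the wider 50% of the lists (exact p = 0.0117). Leaving out single chromosome pairs gave 0.066 without pair 1, 0.064 without pair 2, 0.060 without pair 4, 0.071 without pair 7, 0.063 without pair 8 and 0.064 without pair 9_10, each with an exact p of 0.0625 or 0.0781, and 0.083 without pair 3, 0.085 without pair 5 and 0.081 without pair 6, which still passed (exact p 0.0312, 0.0312 and 0.0391). With 8 pairs the test is coarser, so these omissions also lose precision. The L minus S difference in the share of p300 outside H3K4me3 ranged from -1.89 (without p300 replicate 1, exact p = 0.00391) to 0.076 percentage points with single replicate lists, was 0.045 in the wider 50% of the lists and 0.0023 when an overlap of 50% of the shorter peak was required. The values above 0 did not pass (exact p of 0.855 or more), and neither did the series-wide value of -0.01. The value of -1.89 kept the series-wide sign and passed, so a lower share on L was seen with p300 replicate 2 alone. The cause was not tested. Median widths were 1042 to 1080 bp for H3K4me3 and 214 to 260 bp for p300 in single replicate lists, and by construction 1647 and 295 bp in the wider 50%. Counts per Mb of chromosome length, score thresholds and the gene, start site and motif alternatives were not run, for want of lengths, scores and a fitting annotation.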

Other observations

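The tests in this part were chosen after the data were seen. The p300 peaks were grouped along the chromosomes. When peaks closer than 12.5 kb were joined, 57.7% of the 23017 series-wide p300 peaks on the L and S chromosomes fell in groups of 2 or more, compared with 20.9% when the same number of peaks was placed evenly at random (highest of 200 placements 21.9%). Groups of 5 or more p300 peaks, with a median length of 20.4 kb, numbered 392 on L and 283 on S. Of these large groups, 85.9% overlapped at least 1 H3K4me3 peak, compared with 17.7% for shifted H3K4me3 lists. Of the isolated p300 peaks, 26.3% did, compared with 1.40% (permutation p = 0.005 for both, the smallest that 200 shifts can give). A group was counted from its first to its last peak, gaps included, so its longer interval meets H3K4me3 more often. The shares therefore do not rank large groups against isolated peaks. The log2 L to S ratio was 0.48 ± 0.26 (SD over 9 pairs) for large groups and 0.33 ± 0.10 for isolated peaks, and the difference of 0.16 ± 0.24 did not pass (6 of 9 pairs, exact p = 0.0977).

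Both marks tended to be denser towards the chromosome ends. The outer 10% at each end of the span carried more peaks per Mb than the remainder, by a mean log2 ratio of 0.28 ± 0.34 (SD over 9 pairs, each the mean of its L and S chromosome) for H3K4me3 and of 0.33 ± 0.38 for p300 (7 of 9 pairs and exact sign-flip p = 0.0430 for each). Counting the 18 chromosomes as independent gave exact p values of 0.00549 and 0.00499, which are too small where homeologs resemble each other. Single replicate lists gave 0.32 to 0.37.

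The order of peak-rich and peak-poor regions along an L chromosome resembled that along its S homeolog, which is a hypothesis found and tested on the same lists. With each span divided into 30 bins, the mean Spearman rho of p300 counts between the 9 true partners was 0.38, compared with 0.05 for the 72 other L and S combinations. Among the 362880 possible reassignments of partners a share of 7.72e-05 gave a mean as high. For H3K4me3 the mean was 0.28, compared with 0.01 (share 8.29e-04). For p300, replicates 1 and 2 gave 0.38 and 0.43, compared with 0.07 and 0.16 for the other combinations. For H3K4me3 they gave 0.34 and 0.30, compared with 0.04 and 0.02. The values are consistent with a shared order of marked regions on homeologs, but bins along a chromosome are not independent. The closest likeness was in pair 9_10 for H3K4me3 (rho 0.76) and in pair 6 for p300 (rho 0.67).

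Pair 8 went against this. The p300 rho between 8L and 8S was -0.21 as deposited and 0.48 with 8S read backwards, a gain of 0.69, and for H3K4me3 the values were -0.28 and 0.16. A candidate explanation is that much of 8S runs in the opposite order to 8L in the build of the files. This stays open: 1 of the 72 other combinations gained as much, a permutation p of 0.0274 that became 0.247 when adjusted over the 9 pairs, and 72 combinations are too few for the adjusted value of a single pair to pass. For H3K4me3, pair 3 gained as well, from -0.21 to 0.29. Alignment of 8L and 8S would show whether the order is reversed. The source of such a reversal was not examined. The p300 rho of pair 3 as deposited was -0.01.

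Dense p300 windows were tested for the same likeness, and it was not detected. There were 39 non-overlapping windows of 100 kb with at least 15 p300 peaks on L and 17 on S. The median distance in relative position from a window on L to the nearest on its S partner was 18.4% of the span. It was compared with 18.3% for 10000 reassignments of partners (one-sided permutation p = 0.603). With fewer dense windows on S, many L windows had no S window of their own. The median could therefore miss clusters kept on both homeologs, so the result does not argue against them. Of the L windows, 12 lay within 3% of the span of an S window, a count that was not tested. On chromosome 7, dense windows with 27 peaks on 7L and 26 on 7S lay at 73.8 and 75.7% of the span, and windows with 22 and 31 peaks at 17.2 and 18.8%. These were picked after the positions were seen and are not shown to be homeologous.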
